A study of Arabidopsis thaliana with 18 samples.

How the data were processed

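Whole Arabidopsis thaliana Col-0 seedlings were sampled in 6 groups of 3 independent biological replicates, with and without Enterobacter sp. SA187, at 22 °C (NHS), after 44 °C (HS) and after 37 °C followed by 44 °C (ACC). Per the labels' protocols, seedlings were transferred on day 5, acclimated on day 9 and heated on day 11 under 16 h of light, and RNA was depleted of ribosomal RNA before library preparation. The label gives an age of 15 days at sampling. If that age and day 11 count from the same start, sampling came days after the heating at 44 °C. The interval itself is not given in the sources used here.

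The deposited table of the authors held 1 FPKM value per gene and library for 27371 genes. Per the submitters' processing notes, the tools used were FastQC 0.11.5, Trimmomatic 0.36, TopHat, featureCounts 1.5.1, Cufflinks 2.2.1 and Cuffdiff on TAIR10, and which of them made the FPKM is not given in the sources used here. The authors' comparison tables gave a group FPKM for each side and the log2 fold change of these, per the file headers. They gave a p-value and a q-value of the authors' test, per the file headers, and held only genes marked significant with an absolute log2 fold change over 1. The average column that the authors deposited for HS equalled the mean of replicates 1 and 2 only, and for the other groups that of all 3, so group means were computed here from the libraries. Read counts were not analysed here.

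Depth was estimated from the steps between low FPKM values of 2555 single-exon genes of 1000 to 3000 bp, and 58.8 to 79.3% of those values were whole multiples within 0.15, against 30% by chance. It ran from 15.5 to 107 M fragments, and a gene of low FPKM is therefore less precisely measured in HS+SA187 replicates 2 and 3 than in ACC+SA187 replicate 2. FPKM sums ran from 17.7 to 105 M. Of the tested genes, 27 were listed at exactly 0 in 1 to 9 libraries though the median of their other libraries was at least 10 FPKM, 10 of them organelle genes, and for these each library is given in place of a mean. Of the authors' 6418 loci in the comparison tables, 308 (4.8%) had the same start and end in the TAIR10 annotation used here, and coordinates are given as they stand in the authors' tables. Of the locus IDs, 26703 matched it and 668 did not.

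Values were transformed as log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 3 of 18 libraries were kept, which left 16142. All 6 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level and 12 residual degrees of freedom. There were 9 pairwise contrasts and 3 interactions, the latter being the effect of SA187 in one regime minus that in another. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Groups, contrasts, filter, test, gene lists, the rule for named genes and the variants of the analysis were fixed before the data were examined.

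In each pairwise comparison the text could name called genes with a symbol, a mean of at least 5 FPKM over the 18 libraries and groups that did not overlap. From these the 5 highest and 5 lowest fold changes were taken, with the 2 or 3 called members of each called list that had the largest fold change. For interactions the 3 highest and 3 lowest were taken. HSFA2, HSP101, HSP21, HSP22.0, HSP18.2 and APX2 were always included. The text names part of these, by preference genes whose call held with any library left out.

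There were 30 gene lists, of which 28 had at least 5 tested members. They covered small heat shock proteins, large chaperones, heat shock factors, heat memory, the unfolded protein response, redox, ethylene, abscisic acid, salicylic acid, jasmonate, pattern-triggered immunity, hypoxia, photosynthesis, chlorophyll synthesis and senescence. The others were cell division, auxin, cell wall loosening, sulfur, iron, phosphate, glucosinolates, flavonoids, the circadian clock, root, flower and seed markers, ribosomal proteins chosen by their description, and the genes encoded in chloroplasts and in mitochondria. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 336 tests, which gave 154 calls. With a correlation estimated from the data there were 0 calls, the lowest adjusted p being 0.259. Flower markers and seed markers had 1 tested member each and were left out.

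The variants were median-of-ratios scaling, quantile normalization, nuclear genes rescaled to a common sum with organelle genes left out, and a fit of the groups of the contrast only. Further ones were each library left out, no trend of variance with level, no filter, a threshold of 2-fold, the replicate number as a block, a pseudocount of 0.1 and the estimated correlation. Depth as a covariate, genes listed at 0 left out and 1 further correlation of fold changes were added after the data were seen. Correlations of fold changes were taken across all tested genes, with a jackknife SE over libraries. Where 2 contrasts shared controls, 100 simulations of unchanged groups gave the correlation that sharing alone produces. Differences in organelle share were tested with a two-sided exact permutation test.

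In each of 10 simulated runs 200 of 16142 genes were changed. Between HS+SA187 and HS the test found 71.4% of changes of log2 1 and 94.3% of log2 2, with 4.93% of calls false. Between NHS+SA187 and NHS it found 69.4% and 95.1%, with 4.97% false and 0 wrong signs. A list of 20 genes shifted by 0.5 was found in 2 of 3 and 3 of 3 runs, with 0 and 1 other lists. These rates hold for the simulated noise only. Figures were drawn with matplotlib 3.10.9.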

Results

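RNA sequencing of rRNA-depleted libraries measured gene expression in whole Arabidopsis Col-0 seedlings grown with or without the bacterium Enterobacter sp. SA187, in 6 groups of 3 independent biological replicates. NHS seedlings stayed at 22 °C, HS seedlings met 44 °C directly, and ACC seedlings met 37 °C before 44 °C. NHS+SA187, HS+SA187 and ACC+SA187 were the inoculated groups of the same regimes. Values were FPKM as the authors deposited them, given below as mean ± SD with n = 3, and fold changes are on the log2(FPKM + 1) scale with their SE, which understates the change of low genes. Of 27371 genes, 16142 reached an FPKM of 1 in at least 3 of the 18 libraries and were tested with limma, whose Benjamini-Hochberg adjusted p is given throughout.

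Estimated depth was 17.5, 21.2 and 73.9 M fragments in NHS, 20.9, 48.1 and 27.3 M in HS, and 22.7, 31.8 and 63.4 M in ACC. It was 34.6, 26.2 and 38.4 M in NHS+SA187, 52.1, 15.5 and 17.2 M in HS+SA187, and 22, 107 and 59.8 M in ACC+SA187. Transcripts encoded in chloroplasts and mitochondria made up 93.5 ± 6.95% of all FPKM in NHS, 76.6 ± 17.3% in HS, 82.5 ± 17.2% in ACC, 97.6 ± 0.923% in NHS+SA187, 93.9 ± 5.68% in HS+SA187 and 92.6 ± 1.61% in ACC+SA187. HS differed by −16.8 points from NHS and HS+SA187 by 17.3 points from HS, each with p = 0.2 in a two-sided exact permutation test (adjusted p = 0.6), and 3 against 3 libraries cannot go below 0.1. Over the 9 comparisons p was 0.1 to 0.8 (adjusted p 0.6 to 0.8). Without the 10 top genes the share was 29.1 to 72.4% by library. FPKM divides fragments by gene length, so this is not a share of fragments. On the first principal component, which held 42.9% of the variance, the HS libraries lay at the high end. Placed on the axis from the HS mean (0) to the ACC mean (1), the HS+SA187 libraries lay at 0.17, 0.43 and 0.77, the ACC and ACC+SA187 libraries at 0.87 to 1.09, and the HS libraries at −0.1 to 0.15. NHS libraries lay at 0.8 to 1.11 and NHS+SA187 libraries at 0.7 to 0.88, so the axis did not separate acclimated from unheated seedlings.

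**Figure D1:**
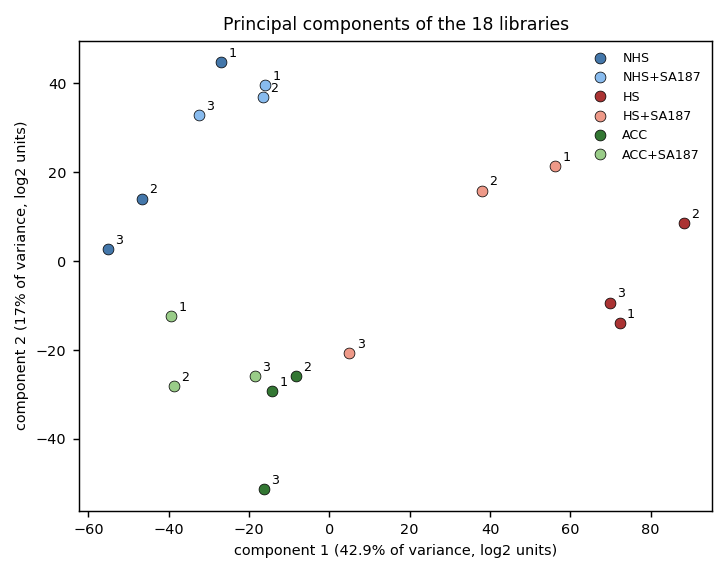
Each point is 1 of the 18 libraries on the first (42.9% of the variance) and second (17%) principal components of the log2(FPKM + 1) values, coloured by group. HS libraries lie at the high end of the first, and HS+SA187 replicate 3 lies near the ACC libraries.

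The comparison of HS with NHS asked what direct exposure to 44 °C did to transcripts of seedlings without the bacterium. Genes of jasmonate synthesis, the wound and defence hormone, were among those with the largest rise: the lipoxygenase gene LOX4 (AT1G72520, TAIR10 chromosome 1, 27308515 to 27312754) went from 1.43 ± 1.86 to 185 ± 16.2 FPKM (log2 fold change 6.51 ± 0.84, limma adjusted p = 2e-05). Chaperones also rose. HSP70-4 (AT3G12580, chromosome 3, 3991261 to 3993792), which binds unfolded proteins, went from 1.63 ± 0.322 to 51.4 ± 7.84 FPKM (4.31 ± 0.23, adjusted p = 2.2e-08). LHCB1.4, which encodes a light-harvesting protein, fell from 3330 ± 965 to 627 ± 92.6 FPKM (−2.38 ± 0.28), though reads of the near-identical LHCB1 copies could be split between them.

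All 20 measured genes of jasmonate synthesis and response rose in HS against NHS, also adjusted over the list alone, with a median log2 fold change of 4.4 (camera adjusted p = 1.41e-11; adjusted p = 0.379 with an estimated correlation). Beside LOX4 these included LOX3 (168 ± 11.4 FPKM in HS, 6.01 ± 0.77) and JAZ1, a repressor of jasmonate responses (372 ± 40.1 FPKM, 5.52 ± 0.6). CYP94B3, which inactivates the hormone, rose from 2.76 ± 3.09 to 178 ± 56.5 FPKM (5.83 ± 0.74). The cyclase gene AOC3 rose from 2.94 ± 2.65 to 159 ± 61.5 FPKM (5.47 ± 0.53). Of 13 small heat shock proteins, which hold other proteins in solution, 12 rose and 1 was not called, and 12 rose adjusted over the list alone (median 2.39, adjusted p = 2.53e-06; adjusted p = 0.4 with an estimated correlation). HSP17.8 went from 0.118 ± 0.0608 to 18.7 ± 13 FPKM (3.93 ± 0.33). Large chaperones and co-chaperones rose in 18 of 19 members, 18 adjusted over the list alone (median 1.23, adjusted p = 1.47e-08; adjusted p = 0.401 with an estimated correlation), among them HSP90.1 (12.8 ± 3.22 against 0.362 ± 0.0254 FPKM). Genes of the unfolded protein response of the endoplasmic reticulum rose in 9 of 14 members, 9 adjusted over the list alone (median 0.79, adjusted p = 0.00242; adjusted p = 0.532 with an estimated correlation). BZIP60, a transcription factor of that response, rose from 9.83 ± 4.87 to 44.8 ± 12.1 FPKM (2.13 ± 0.43). BZIP28, released from the membrane under stress, rose from 7.05 ± 1.27 to 21.8 ± 1.85 FPKM (1.51 ± 0.19).

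Among 21 genes of abscisic acid and dehydration response, 20 rose and 1 was not called, and 20 rose adjusted over the list alone (median 1.57, adjusted p = 3.04e-05; adjusted p = 0.379 with an estimated correlation). NCED3, a rate-setting enzyme of abscisic acid synthesis, went from 2.02 ± 0.692 to 33.1 ± 6.33 FPKM (3.51 ± 0.42, adjusted p = 1.1e-05). The dehydrin gene ERD10 rose from 35.7 ± 11.6 to 277 ± 53.9 FPKM (2.95 ± 0.44). Pattern-triggered immunity rose in 14 of 17 genes, 14 adjusted over the list alone (median 1.76, adjusted p = 0.00115; adjusted p = 0.567 with an estimated correlation), including RBOHD, an oxidase that makes reactive oxygen at the plasma membrane (81.4 ± 20 against 5.91 ± 2.92 FPKM). All 16 genes of glucosinolate synthesis rose, also adjusted over the list alone (median 2.51, adjusted p = 1.07e-10; adjusted p = 0.379 with an estimated correlation). CYP79F1 (AT1G16410, chromosome 1, 5608807 to 5611426), which starts the synthesis of methionine-derived glucosinolates, went from 0.521 ± 0.147 to 36.7 ± 5.92 FPKM (4.62 ± 0.35, adjusted p = 2.2e-07). CYP79B2, which starts the tryptophan-derived branch, rose from 3.96 ± 0.17 to 104 ± 3.51 FPKM (4.41 ± 0.28). Sulfur assimilation rose in 7 of 10 members, 7 adjusted over the list alone (median 1.24, adjusted p = 0.0136; adjusted p = 0.61 with an estimated correlation). APR1, which reduces activated sulfate, rose from 0.698 ± 0.0459 to 12.3 ± 1.25 FPKM (2.96 ± 0.29). Its relative APR3 rose from 2.16 ± 0.588 to 21.1 ± 3.77 FPKM (2.81 ± 0.28). Flavonoid and anthocyanin synthesis rose in 11 of 12, and in 12 adjusted over the list alone (median 1.53, adjusted p = 4.52e-05; adjusted p = 0.422 with an estimated correlation), with the anthocyanin enzyme DFR at 14.9 ± 2.52 against 1.59 ± 0.555 FPKM.

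Nuclear-encoded photosynthesis genes fell in 23 of 31 members and rose in none, 23 adjusted over the list alone (median −0.77, adjusted p = 1.13e-12; adjusted p = 0.294 with an estimated correlation). The photosystem I subunit gene PSAF went from 946 ± 82.6 to 269 ± 49 FPKM (−1.82 ± 0.23). Chlorophyll synthesis fell in 6 of 13 genes, 6 adjusted over the list alone (median −0.40, adjusted p = 0.000616; adjusted p = 0.259 with an estimated correlation), HEMA1, which opens the pathway, from 106 ± 4.12 to 29.9 ± 5.64 FPKM. PORB, which reduces protochlorophyllide in light, fell from 111 ± 20.5 to 34 ± 5.36 FPKM (−1.67 ± 0.19). Outside these lists, the fructose-bisphosphate aldolase gene FBA5 (−4.04 ± 0.32, 7.97 ± 2.23 FPKM in HS) and PAR1, a repressor of shade responses (−3.54 ± 0.23, 1.61 ± 0.384 FPKM in HS), fell too. The kinase gene CIPK20 fell from 35.3 ± 3.77 to 2.4 ± 1.7 FPKM (−3.52 ± 0.3). Root markers moved too: 7 of 14 fell and 1 rose, also adjusted over the list alone (median −0.40, adjusted p = 0.0007; adjusted p = 0.525 with an estimated correlation), and CASP1, a protein of the endodermal barrier, was at 0.331 ± 0.296 against 8.53 ± 0.7 FPKM. The aquaporin gene TIP2;3 fell from 8.65 ± 1.28 to 0.225 ± 0.154 FPKM (−2.98 ± 0.39). Chloroplast-encoded genes fell in 9 of 86, 3 adjusted over the list alone (median −0.20, adjusted p = 2.64e-05; adjusted p = 0.602 with an estimated correlation), with medians from −0.457 without HS replicate 2 to −0.0507 without HS replicate 3 (−0.123, −0.355 and −0.113 without NHS replicate 1, NHS replicate 3 and HS replicate 1). Mitochondrion-encoded genes rose in 45 of 120, 42 adjusted over the list alone (median 0.57, adjusted p = 0.0276; adjusted p = 0.833 with an estimated correlation), a call lost without HS replicate 1 (adjusted p = 0.0617), HS replicate 3 (0.0729) or NHS replicate 1 (0.496). In the circadian clock list 4 genes rose and 5 fell, also adjusted over the list alone (median −0.17, adjusted p = 0.0497; adjusted p = 0.519 with an estimated correlation), and that call was lost without HS replicate 2 (0.0923) or NHS replicate 3 (0.0605). PRR7, a clock repressor, fell to 5.06 ± 0.413 FPKM (−1.65 ± 0.16). LHY, a morning gene, rose from 2.9 ± 0.22 to 10.3 ± 1.66 FPKM (1.53 ± 0.14).

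Lists without a call between HS and NHS are given as counts of members up and down. They were heat shock factors (8 and 1), heat memory genes (5 and 1), redox and antioxidant genes (9 and 4, median 1.46), ethylene (10 and 2), salicylic acid (8 and 0), hypoxia core genes (5 and 1) and senescence (10 and 4, median 0.90). The others were cell division (8 and 0), auxin (5 and 2, median 0.13), cell wall loosening (4 and 5), iron (8 and 2), phosphate starvation (1 and 2, median −0.10) and ribosomal proteins (46 and 2). Flower markers and seed and embryo markers had 1 tested member each and were not tested as lists.

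Camera called 15 lists between HS and NHS, 10 up and 5 down (adjusted p = 0.259 to 0.833 with an estimated correlation). Between HS and NHS, limma called 6661 genes, 5113 higher and 1548 lower, and for 51.2% of genes the groups did not overlap, against 10% by chance. The share higher, 76.8%, was 56% after median-of-ratios scaling and 42.8% after quantile normalization, as the median of all genes moved from 0.21 to 0.025 and −0.083. A rescaling to a common sum of nuclear-encoded FPKM, of which the single gene AT2G01021 held 54.4 to 95.2%, moved that median to −0.18 and left 115 calls.

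**Figure D2:**
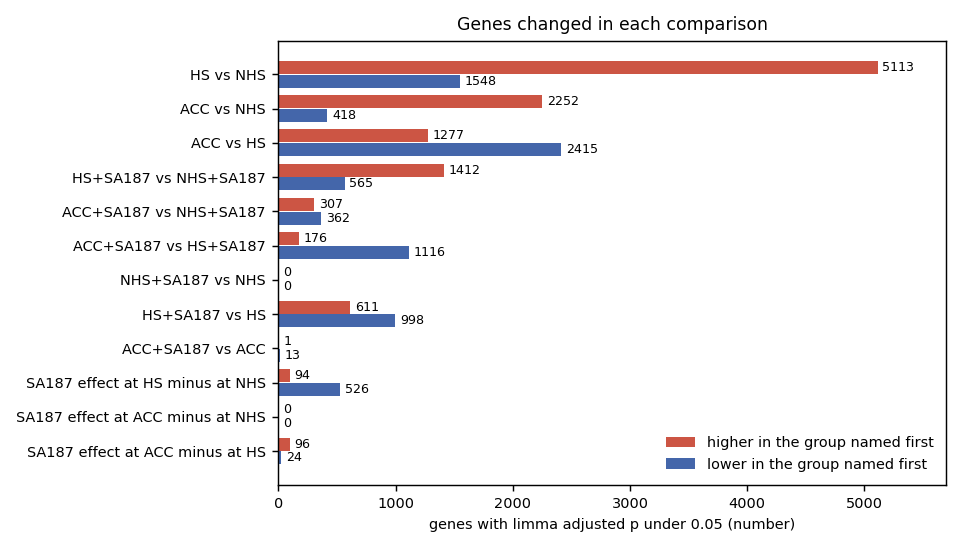
Bars give the number of genes called higher and lower by limma (adjusted p under 0.05) in each of the 12 contrasts. HS against NHS has the most, 5113 higher and 1548 lower, and NHS+SA187 against NHS has 0.

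Acclimated seedlings without the bacterium were set against NHS to ask what remained or changed after 37 °C and then 44 °C. The lipid transfer protein gene LTP2 went from 4.53 ± 2.57 to 103 ± 35.8 FPKM (log2 fold change 4.32 ± 0.52, adjusted p = 0.00013). BHLH100, a regulator of iron uptake, went from 0.164 ± 0.0689 to 20.8 ± 8.89 FPKM (4.14 ± 0.66, adjusted p = 0.00093). The dark-inducible gene DIN1 fell from 227 ± 79.8 to 33.5 ± 14.4 FPKM (−2.78 ± 0.5) and GDPD2, which releases phosphate from membrane lipid, from 72.8 ± 23.9 to 8.1 ± 3.61 FPKM (−3.05 ± 0.41). The trypsin inhibitor gene TI1 rose from 0.657 ± 0.547 to 25.8 ± 19 FPKM (3.84 ± 0.57). HSP70-4 was at 23.2 ± 5.07 FPKM (3.18 ± 0.23, adjusted p = 2.2e-06).

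In ACC against NHS, 15 of 19 large chaperones rose, 17 adjusted over the list alone (median 0.88, adjusted p = 1.01e-10; adjusted p = 0.379 with an estimated correlation), with HSP90.1 at 6.74 ± 1.01 FPKM (2.5 ± 0.16). Small heat shock proteins rose in 11 of 13, 12 adjusted over the list alone (median 1.07, adjusted p = 9.63e-06; adjusted p = 0.4 with an estimated correlation), HSP17.8 to 4.68 ± 0.987 FPKM. The endoplasmic reticulum list rose in 8 of 14, 9 adjusted over the list alone (median 0.52, adjusted p = 0.000797; adjusted p = 0.519 with an estimated correlation), with the lumenal chaperone BIP1 at 24.5 ± 2.5 against 10.2 ± 1.22 FPKM. Calnexin CNX1, which folds glycoproteins there, rose from 8.05 ± 1.63 to 20.8 ± 2.91 FPKM (1.28 ± 0.22). All 16 glucosinolate genes rose, also adjusted over the list alone (median 1.69, adjusted p = 1.85e-15; adjusted p = 0.294 with an estimated correlation), CYP79B2 to 43 ± 12.8 FPKM (3.11 ± 0.28). Sulfur assimilation rose in 7 of 10, 8 adjusted over the list alone (median 0.83, adjusted p = 0.000662; adjusted p = 0.519 with an estimated correlation), and flavonoid synthesis in 8 of 12, 11 adjusted over the list alone (median 0.89, adjusted p = 9.32e-06; adjusted p = 0.4 with an estimated correlation). Cell division genes rose in 10 of 17 and 16 adjusted over the list alone (median 0.57, adjusted p = 1.04e-05; adjusted p = 0.519 with an estimated correlation), led by TSO2, a ribonucleotide reductase subunit (56.7 ± 9.59 against 7.37 ± 0.539 FPKM, 2.77 ± 0.33). The cyclin gene CYCD3;1 rose from 3.49 ± 0.68 to 8.71 ± 2.1 FPKM (1.1 ± 0.2). Jasmonate (4 up, median 0.38), abscisic acid (9 up, median 0.34) and iron genes (7 up, median 0.36) were not called as lists.

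Camera called 14 lists between ACC and NHS, 9 up and 5 down (adjusted p = 0.294 to 0.872 with an estimated correlation). Root markers had a camera direction of down, with 4 of 14 lower and 2 higher, and 5 lower and 4 higher adjusted over the list alone (median −0.057, adjusted p = 0.0185; adjusted p = 0.622 with an estimated correlation), a call lost without ACC replicate 3 (adjusted p = 0.0722). That median was −0.022, −0.11 and 0.0544 without NHS replicate 1, 2 or 3, and −0.301 and 0.137 without ACC replicate 2 or 3. The root aquaporin gene TIP2;2 fell from 72.1 ± 13.3 to 26.1 ± 15.2 FPKM (−1.55 ± 0.33). Ethylene genes lay below other genes, with 4 of 26 lower, 4 adjusted over the list alone (median 0.059 but mean −0.32, adjusted p = 0.00809; adjusted p = 0.549 with an estimated correlation), a call lost without ACC replicate 2 (0.0915). The median was 0.124 and 0.0248 without NHS replicate 1 or 2, and 0.105 and 0.0283 without ACC replicate 1 or 2. Hypoxia core genes lay below other genes, with 1 of 10 lower and 1 higher, also adjusted over the list alone (median −0.040, adjusted p = 0.0383; adjusted p = 0.531 with an estimated correlation), a call lost without ACC replicate 2 (0.0857) or NHS replicate 2 (0.0772) or 3 (0.0819). The median was −0.108 and −0.0213 without NHS replicate 2 or 3, and 0.0357 and −0.155 without ACC replicate 1 or 2. Chloroplast-encoded genes lay below other genes, with 1 of 86 lower (ORF31), 1 adjusted over the list alone (median −0.12, adjusted p = 1.39e-05; adjusted p = 0.596 with an estimated correlation). Their median was 0.0216 and −0.203 without NHS replicate 1 or 3, and −0.0683, −0.291 and 0.241 without ACC replicate 1, 2 or 3.

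For nuclear-encoded photosynthesis the camera direction was down (adjusted p = 6.53e-06; adjusted p = 0.425 with an estimated correlation) with 0 of 31 members called, 0 adjusted over the list alone, a median of −0.20 and a mean of 0.087, so median and mean differed in sign. LHCB1.3 and RBCS1A were listed at 0 FPKM in NHS replicate 3, and without these 2 members the mean was −0.214 and the median −0.228. Without NHS replicate 3 the median was −0.1. After quantile normalization the call of the list photosynthesis, nuclear-encoded in ACC vs NHS was lost (adjusted p = 0.0886). Limma called 2670 genes between ACC and NHS, 2252 higher and 418 lower, and 35.2% of genes had groups that did not overlap (10% by chance). The share higher was 84.3% as deposited, 53.8% after median-of-ratios scaling and 50.9% after quantile normalization, the median of all genes moving from 0.185 to 0.0132 and −0.00783, and to −0.041 with 10 calls when nuclear genes were rescaled. The count was 1451 without NHS replicate 1, 1637 without NHS replicate 2 and 1331 without ACC replicate 3.

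The direct contrast of ACC with HS asked how prior acclimation changed the state after 44 °C. Jasmonate and defence transcripts were lower in ACC: LOX4 was at 0.478 ± 0.0949 against 185 ± 16.2 FPKM in HS (−6.97 ± 0.84, adjusted p = 3.7e-05), and WRKY40, a defence transcription factor, at 0.863 ± 0.342 against 135 ± 37.5 FPKM (−6.17 ± 0.84, adjusted p = 9.5e-05). RRTF1, a redox-responsive transcription factor, was at 0.0322 ± 0.0112 against 117 ± 40.4 FPKM (−6.78 ± 1.14, adjusted p = 0.00044). LHCB1.4 was higher, at 1830 ± 326 against 627 ± 92.6 FPKM (1.54 ± 0.28, LHCB1 copies again uncertain). PAR1 (2.37 ± 0.23, 12.6 ± 2.96 FPKM in ACC) and the iron superoxide dismutase gene FSD1 (2.57 ± 0.43, 37.1 ± 30.2 FPKM) were higher as well. ENH1, a rubredoxin of the chloroplast, was at 7.79 ± 2.78 against 0.766 ± 0.207 FPKM (2.28 ± 0.22).

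Of 20 jasmonate genes, 19 were lower in ACC than in HS and 1 was not called, and 20 were lower adjusted over the list alone (median −3.8, adjusted p = 3.61e-16; adjusted p = 0.294 with an estimated correlation). Pattern-triggered immunity was lower in 14 of 17, 14 adjusted over the list alone (median −1.73, adjusted p = 3.69e-07; adjusted p = 0.401 with an estimated correlation), and salicylic acid and systemic resistance in 7 of 12, 7 adjusted over the list alone (median −0.76, adjusted p = 0.0014; adjusted p = 0.54 with an estimated correlation). WRKY33, a regulator of camalexin synthesis, was at 3.34 ± 0.499 against 104 ± 19.7 FPKM (−4.59 ± 0.69). CBP60G, which drives salicylic acid synthesis, was at 0.719 ± 0.268 against 6.14 ± 2.1 FPKM (−2.02 ± 0.48). Abscisic acid response fell in 10 of 21, with 11 lower and 1 higher adjusted over the list alone (median −0.80, adjusted p = 0.000349; adjusted p = 0.4 with an estimated correlation), −0.397 without HS replicate 2 and −0.529 without ACC replicate 1, NCED3 to 1.17 ± 0.107 FPKM (−3.95 ± 0.42). Small heat shock proteins were lower in 9 of 13, 11 adjusted over the list alone (median −1.36, adjusted p = 2.63e-05; adjusted p = 0.421 with an estimated correlation), and large chaperones in 9 of 19, 11 adjusted over the list alone (median −0.41, adjusted p = 0.000161; adjusted p = 0.559 with an estimated correlation). HSP70b was at 3.53 ± 0.671 against 14.3 ± 5.51 FPKM (−1.69 ± 0.23). HSP17.6C was at 1.19 ± 1.03 against 7.1 ± 2.7 FPKM (−1.94 ± 0.3). Heat shock factors and co-regulators fell in 6 of 13 and rose in 1, with 9 lower and 1 higher adjusted over the list alone (median −0.48, adjusted p = 0.0117; adjusted p = 0.519 with an estimated correlation), the factor HSFA4A to 3.03 ± 1.23 from 26.8 ± 5.01 FPKM. DREB2A, which links drought and heat, was at 2.08 ± 0.714 against 12.9 ± 3.58 FPKM (−2.16 ± 0.47). Glucosinolate genes were lower in 8 of 16, 12 adjusted over the list alone (median −0.76, adjusted p = 0.000141; adjusted p = 0.532 with an estimated correlation). The sulfotransferase gene SOT16 was at 39.1 ± 3.73 against 149 ± 36.5 FPKM (−1.88 ± 0.34). CYP83B1 was at 82.5 ± 5.51 against 205 ± 14 FPKM (−1.3 ± 0.25).

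Chlorophyll synthesis was higher in ACC than in HS in 6 of 13 genes, 8 adjusted over the list alone (median 0.67, adjusted p = 7.58e-05; adjusted p = 0.259 with an estimated correlation), HEMA1 at 89.5 ± 19.8 FPKM (1.54 ± 0.25). PORB was at 95.6 ± 16.4 against 34 ± 5.36 FPKM (1.46 ± 0.19). Photosynthesis was higher in 12 of 31, 20 adjusted over the list alone (median 0.62, adjusted p = 5.65e-08; adjusted p = 0.379 with an estimated correlation). PSAF was at 741 ± 95.8 against 269 ± 49 FPKM (1.47 ± 0.23). Root markers were higher in 3 of 14, 3 adjusted over the list alone (median 0.45, 0.169 without ACC replicate 2, adjusted p = 0.00322; adjusted p = 0.559 with an estimated correlation), CASP1 at 3.13 ± 2.28 FPKM (1.52 ± 0.31). Of the 15 lists called between ACC and HS, 4 were up and 11 down (adjusted p = 0.259 to 0.833 with an estimated correlation). Limma called 3692 genes, 1277 higher and 2415 lower in ACC, and the groups of 32% of genes did not overlap (10% by chance). The share higher was 34.6%, 37.7% after median-of-ratios scaling and 53.6% after quantile normalization, where the median of all genes moved from 0.014 to 0.12, and nuclear rescaling moved it to 0.18 with 92 calls.

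HS+SA187 was set against NHS+SA187 to follow the response to 44 °C in inoculated seedlings. The jasmonate-regulated gene JRG21 went from 0.0551 ± 0.0232 to 18.8 ± 2.54 FPKM (4.22 ± 0.24, adjusted p = 2.7e-07), and PRX52, a peroxidase, from 0.0563 ± 0.0173 to 18.1 ± 2.96 FPKM (4.16 ± 0.28). LOX2, a chloroplast lipoxygenase of jasmonate synthesis, rose from 11.3 ± 2.26 to 110 ± 26.8 FPKM (3.17 ± 0.32), and HSP70-4 from 2.52 ± 1.32 to 16.7 ± 2.8 FPKM (2.38 ± 0.23). DIN1 fell from 202 ± 15.1 to 18.6 ± 3.74 FPKM (−3.38 ± 0.5), and FBA5 from 109 ± 22.2 to 14.8 ± 3.71 FPKM (−2.8 ± 0.32). EARLI1, a lipid transfer-like protein of the cell wall, rose from 1.88 ± 0.992 to 34.4 ± 13.6 FPKM (3.6 ± 0.48).

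Jasmonate genes rose in 12 of 20 members, 16 adjusted over the list alone, between NHS+SA187 and HS+SA187 (median 1.99, 1.02 without HS+SA187 replicate 1, adjusted p = 9.82e-09; adjusted p = 0.4 with an estimated correlation). CORI3, a coronatine-induced gene, rose from 0.509 ± 0.148 to 13.5 ± 1.09 FPKM (3.26 ± 0.23). Large chaperones rose in 13 of 19, 16 adjusted over the list alone (median 0.69, adjusted p = 4.5e-09; adjusted p = 0.4 with an estimated correlation), and small heat shock proteins in 8 of 13, 11 adjusted over the list alone (median 1.05, adjusted p = 1.65e-05; adjusted p = 0.401 with an estimated correlation). HSP90.1 rose from 0.552 ± 0.0287 to 5.55 ± 0.603 FPKM (2.07 ± 0.16). The endoplasmic reticulum list rose in 7 of 14, 8 adjusted over the list alone (median 0.54, adjusted p = 6.92e-05; adjusted p = 0.422 with an estimated correlation). BIP2 rose from 8.72 ± 1.93 to 18.9 ± 2.29 FPKM (1.05 ± 0.2). All 16 glucosinolate genes rose, also adjusted over the list alone (median 1.57, adjusted p = 1.75e-15; adjusted p = 0.294 with an estimated correlation), CYP79F1 to 20.6 ± 6.82 FPKM (3.02 ± 0.35). Iron uptake and storage genes rose in 6 of 17, 7 adjusted over the list alone (median 0.97, 0.63 without HS+SA187 replicate 3, adjusted p = 0.0208; adjusted p = 0.616 with an estimated correlation), BHLH100 among them (13 ± 9.78 FPKM, 3.34 ± 0.66). Photosynthesis fell in 3 of 31, 7 adjusted over the list alone (median −0.50, adjusted p = 1.76e-10; adjusted p = 0.379 with an estimated correlation). Root markers fell in 5 of 14 and rose in 1, with 6 lower and 4 higher adjusted over the list alone (median −0.20, adjusted p = 0.00429; adjusted p = 0.567 with an estimated correlation), and that median was −0.0191 and −0.42 without NHS+SA187 replicate 1 or 2 and −0.0815 without HS+SA187 replicate 2.

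There were 14 lists called, 11 up and 3 down (adjusted p = 0.294 to 0.75 with an estimated correlation). Limma called 1977 genes between HS+SA187 and NHS+SA187, 1412 higher and 565 lower, with 30.9% of genes not overlapping (10% by chance). The share higher was 71.4%, 52.7% after median-of-ratios scaling and 45% after quantile normalization, the median of all genes moving from 0.13 to 0.022 and −0.018, and to 0.33 with 119 calls under nuclear rescaling. The count was 1251, 937 and 1091 without NHS+SA187 replicate 2, NHS+SA187 replicate 3 and HS+SA187 replicate 2. Across genes, which are not independent replicates, the responses to 44 °C with and without the bacterium correlated at r = 0.773 (jackknife SE 0.13), from libraries with no overlap. They shared 1241 higher and 511 lower genes, against 447 and 54.2 for independent lists.

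ACC+SA187 against NHS+SA187 gave the response of inoculated seedlings to acclimation followed by 44 °C. NIT2, a nitrilase, rose from 4.83 ± 1.4 to 33.2 ± 9.59 FPKM (2.54 ± 0.3, adjusted p = 0.00053) and JRG21 from 0.0551 ± 0.0232 to 4.49 ± 2.55 FPKM (2.28 ± 0.24). DIC2, a mitochondrial carrier of dicarboxylates, fell from 62.6 ± 36.4 to 1.54 ± 0.675 FPKM (−4.54 ± 0.75, adjusted p = 0.0056), and PHI1, a phosphate-responsive gene, from 91.8 ± 13 to 9.05 ± 2.34 FPKM (−3.23 ± 0.54). The ethylene response factor gene ERF105 fell from 37.2 ± 4.13 to 1.9 ± 1.09 FPKM (−3.79 ± 0.63).

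Glucosinolate genes rose in 11 of 16, 14 adjusted over the list alone, with a median of 1.06 that was −0.053 with nuclear genes rescaled (adjusted p = 4.36e-11; adjusted p = 0.379 with an estimated correlation). CYP79F1 was at 9.76 ± 5.83 against 1.65 ± 0.803 FPKM (1.94 ± 0.35). Large chaperones rose in 3 of 19, 10 adjusted over the list alone, with a median of 0.38 that was −0.49 with nuclear genes rescaled (adjusted p = 4.34e-07; adjusted p = 0.472 with an estimated correlation), and HSP90.1 was at 2.89 ± 0.664 against 0.552 ± 0.0287 FPKM. Pattern-triggered immunity fell in 2 of 17, 5 adjusted over the list alone (median −0.27, −0.62 without NHS+SA187 replicate 3, adjusted p = 0.00379; adjusted p = 0.61 with an estimated correlation). Mitochondrion-encoded genes rose in 1 of 120, 0 adjusted over the list alone (median 0.45, adjusted p = 2.97e-05; adjusted p = 0.652 with an estimated correlation). The list chosen by the words for cytosolic ribosomal proteins rose in 2 of 297, 0 adjusted over the list alone, with a median of 0.27 that was −0.92 with nuclear genes rescaled and 0.17 without ACC+SA187 replicate 3 (adjusted p = 2.08e-05; adjusted p = 0.744 with an estimated correlation). Both members that moved, RPL15 (AT3G25920, 0.86 ± 0.21) and emb1473 (AT1G78630, 0.69 ± 0.15), encode ribosomal proteins of the plastid, and they were at −0.46 and −0.63 with nuclear genes rescaled. Their calls were lost in most refits with a library left out, for example without ACC+SA187 replicate 2 (adjusted p = 0.158 and 0.119), NHS+SA187 replicate 1 (0.107 and 0.0637), NHS+SA187 replicate 2 (0.0766 and 0.0658), NHS+SA187 replicate 3 (0.074 and 0.0583) or ACC+SA187 replicate 3 (0.107 and 0.0897), and RPL15 also without ACC+SA187 replicate 1 (0.0507).

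There were 12 lists called, 7 up and 5 down, root markers among the latter (median −0.27, 2 of 14 lower, 6 lower and 2 higher adjusted over the list alone, adjusted p = 0.0218; adjusted p = 0.638 with an estimated correlation). The root marker call was lost without ACC+SA187 replicate 3 (0.0577) or NHS+SA187 replicate 1 (0.0769), and the median was −0.115 and −0.477 without NHS+SA187 replicate 1 or 2. Limma called 669 genes between ACC+SA187 and NHS+SA187, 307 higher and 362 lower, with 32.7% of genes not overlapping (10% by chance). The share higher was 45.9%, and 27.4% after median-of-ratios scaling, while nuclear rescaling moved the median of all genes from 0.071 to −0.88 and left 44 calls. The count was 294, 169 and 307 without NHS+SA187 replicate 1, 2 or 3, and 101 and 126 without ACC+SA187 replicate 2 or 3. Across genes, again not independent replicates, the acclimated responses with and without the bacterium correlated at r = 0.611 (jackknife SE 0.16) and shared 258 higher and 151 lower genes, against 42.8 and 9.37 for independent lists.

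ACC+SA187 against HS+SA187 asked about acclimation within inoculated seedlings. Defence and hormone transcripts were lower after acclimation: ZAT10, a zinc finger repressor, was at 8.24 ± 2.71 against 339 ± 250 FPKM (−4.8 ± 0.81, adjusted p = 0.006), and ERF105 at 1.9 ± 1.09 against 71.2 ± 44 FPKM (−4.44 ± 0.63, adjusted p = 0.0044). JAZ5 was at 0.754 ± 0.211 against 28.4 ± 28.9 FPKM (−3.48 ± 0.58), and ACS6, an enzyme of ethylene synthesis, at 2.61 ± 0.818 against 76.4 ± 58 FPKM (−4.06 ± 0.73). DIC2 was lower as well (−5.35 ± 0.75, 133 ± 93.5 FPKM in HS+SA187). CAF1a, which shortens poly(A) tails, was at 2.86 ± 1.53 against 102 ± 61 FPKM (−4.56 ± 0.7). WRKY40 was at 1.2 ± 0.237 against 77.5 ± 60.7 FPKM (−4.71 ± 0.84).

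Jasmonate genes were lower in 11 of 20, 16 adjusted over the list alone (median −1.77, adjusted p = 1.75e-10; adjusted p = 0.379 with an estimated correlation), and pattern-triggered immunity in 10 of 17, 14 adjusted over the list alone (median −1.51, adjusted p = 7.13e-09; adjusted p = 0.379 with an estimated correlation). Ethylene synthesis and response fell in 7 of 26, 8 adjusted over the list alone (median −0.24, −0.162 without ACC+SA187 replicate 1, adjusted p = 0.00175; adjusted p = 0.519 with an estimated correlation). Iron genes were lower in 6 of 17 and higher in 1, with 10 lower and 2 higher adjusted over the list alone (median −1.14, adjusted p = 0.00129; adjusted p = 0.519 with an estimated correlation). Small heat shock proteins were lower in 1 of 13, 5 adjusted over the list alone (median −0.70, adjusted p = 0.00309; adjusted p = 0.549 with an estimated correlation). Chlorophyll synthesis was higher in 2 of 13, 4 adjusted over the list alone, with a median of 0.26 that was −1.06 with nuclear genes rescaled and 0.395 without HS+SA187 replicate 3 (adjusted p = 0.000349; adjusted p = 0.259 with an estimated correlation).

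Of the 16 lists called, 4 were up and 12 down (adjusted p = 0.259 to 0.833 with an estimated correlation). Between ACC+SA187 and HS+SA187, limma called 1292 genes, 176 higher and 1116 lower, and 26.2% of genes did not overlap (10% by chance). The share higher was 13.6%, and 44.4% after quantile normalization, which moved the median of all genes from −0.038 to 0.096, while nuclear rescaling moved it to −1.2 with 620 calls. The count was 235, 291 and 2158 without HS+SA187 replicate 1, 2 or 3, and 166 and 186 without ACC+SA187 replicate 1 or 2.

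NHS+SA187 against NHS asked what the bacterium did to unstressed seedlings. Glucosinolate genes had a median log2 fold change of 0.39 and a camera direction of up, with 0 of 16 called over all genes and 3 adjusted over the list alone (adjusted p = 7.08e-06; adjusted p = 0.493 with an estimated correlation). Without NHS+SA187 replicate 1 that median was 0.168. CYP79F1 was at 1.65 ± 0.803 against 0.521 ± 0.147 FPKM. Salicylic acid genes had a median of 0.35 with 0 of 12 called and 1 adjusted over the list alone (adjusted p = 0.000544; adjusted p = 0.525 with an estimated correlation). Heat memory genes showed no difference that passed: HSP101 was at 0.799 ± 0.0495 against 0.752 ± 0.268 FPKM (0.05 ± 0.18, adjusted p = 0.97).

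Camera called 8 lists here, 4 up and 4 down (adjusted p = 0.4 to 0.833 with an estimated correlation). Limma called 0 genes, with 711 at an unadjusted p under 0.05 (807 by chance), and 11.5% of genes did not overlap (10% by chance). Nuclear rescaling gave 14 calls as the median of all genes moved from 0.0955 to 0.735, and quantile normalization moved it to −0.042 with 0 calls. The authors' Cuffdiff tables list 304 genes here, 286 higher in NHS+SA187, with WRKY33 at 61.4 against 18.3 FPKM and CYP79F1 at 2.96 against 1.02 FPKM.

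**Figure D3:**
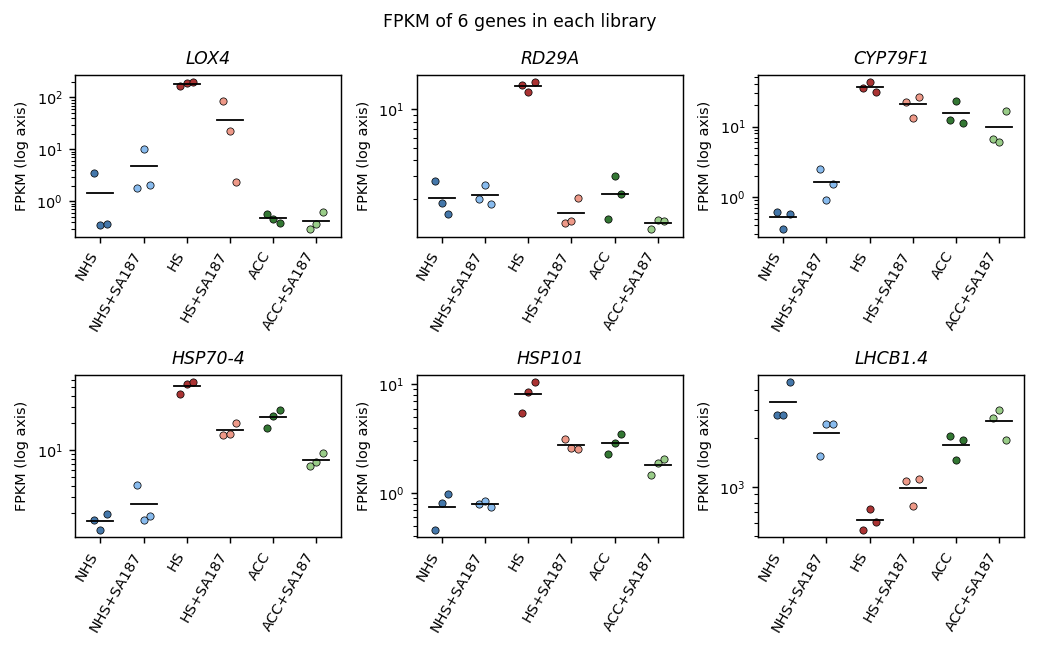
Points give FPKM per library (log axis) of LOX4, RD29A, CYP79F1, HSP70-4, HSP101 and LHCB1.4 in the 6 groups, and lines the group means. LOX4 runs from 2.37 to 85.7 FPKM in HS+SA187 and from 167 to 199 FPKM in HS.

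HS+SA187 against HS asked what the bacterium changed under direct 44 °C. EXPA1, an expansin that loosens cell walls (AT1G69530, chromosome 1, 26141836 to 26143500), rose from 8.68 ± 1.61 to 55.7 ± 17.3 FPKM (2.52 ± 0.27, adjusted p = 4.8e-05), and GASA6, a gibberellin-regulated peptide gene, from 12.3 ± 5.01 to 62.8 ± 16.7 FPKM (2.32 ± 0.34). RD29A, a marker of dehydration response, fell from 15.1 ± 1.38 to 1.55 ± 0.41 FPKM (−2.67 ± 0.19, adjusted p = 2.2e-06). AOC1, an enzyme of jasmonate synthesis (AT3G25760, chromosome 3, 9403883 to 9405250), fell from 150 ± 44.9 to 13.7 ± 15.9 FPKM (−3.88 ± 0.5, adjusted p = 0.00024). The transcription factor gene MYB74 fell from 28.7 ± 17.5 to 1.15 ± 0.334 FPKM (−3.59 ± 0.34), and AIR1 rose from 0.411 ± 0.244 to 12.2 ± 5.58 FPKM (3.12 ± 0.61). RAP2.6, a stress-responsive transcription factor gene, fell from 61.9 ± 36.9 to 4.13 ± 2.83 FPKM (−3.54 ± 0.53).

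Jasmonate genes were lower in HS+SA187 than in HS in 14 of 20 members, 17 adjusted over the list alone (median −2.18, adjusted p = 9.41e-13; adjusted p = 0.379 with an estimated correlation). Replicates spread widely there: LOX4 was at 85.7, 23 and 2.37 FPKM in HS+SA187 (−3.28 ± 0.84, adjusted p = 0.02), and its call was lost in 5 of the refits with a library left out (adjusted p = 0.0536 to 0.065). CYP94B3 fell from 178 ± 56.5 to 24.1 ± 26.7 FPKM (−3.53 ± 0.74). Abscisic acid response fell in 11 of 21, 13 adjusted over the list alone, with a median of −0.97 that was 0.55 with nuclear genes rescaled and −0.603 without HS replicate 2 (adjusted p = 3.72e-09; adjusted p = 0.259 with an estimated correlation). ERD10 fell from 277 ± 53.9 to 64.7 ± 52.4 FPKM (−2.41 ± 0.44). Small heat shock proteins fell in 9 of 13 and rose in 1, with 12 lower and 1 higher adjusted over the list alone, and their median of −1.18 was 0.093 with nuclear genes rescaled (adjusted p = 5.58e-08; adjusted p = 0.379 with an estimated correlation). HSP17.8 went to 3.89 ± 1.07 FPKM (−1.82 ± 0.33). HSP17.6C went from 7.1 ± 2.7 to 1.27 ± 0.463 FPKM (−1.79 ± 0.3). Large chaperones fell in 10 of 19, 11 adjusted over the list alone, with a median of −0.63 that was 0.89 with nuclear genes rescaled (adjusted p = 9.97e-10; adjusted p = 0.4 with an estimated correlation). HSP70b went to 3.13 ± 0.697 from 14.3 ± 5.51 FPKM (−1.83 ± 0.23), and HSP70-4 to 16.7 ± 2.8 from 51.4 ± 7.84 FPKM (−1.57 ± 0.23, and 0.3 with nuclear genes rescaled).

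Heat memory genes fell in 3 of 7 between HS and HS+SA187, with 4 lower and 1 higher adjusted over the list alone and a median of −0.74 that was 0.38 with nuclear genes rescaled (adjusted p = 0.00753; adjusted p = 0.401 with an estimated correlation). HSP101, which pulls proteins out of aggregates, was at 2.74 ± 0.327 against 8.17 ± 2.53 FPKM (−1.26 ± 0.18, adjusted p = 0.00058, and 0.37 with nuclear genes rescaled). Hypoxia core genes fell in 5 of 10, 5 adjusted over the list alone, with a median of −0.48 that was 0.73 with nuclear genes rescaled (adjusted p = 0.00275; adjusted p = 0.4 with an estimated correlation). Glucosinolate genes fell in 2 of 16, 4 adjusted over the list alone, with a median of −0.59 that was 1.21 with nuclear genes rescaled (adjusted p = 0.0016; adjusted p = 0.602 with an estimated correlation). Chlorophyll synthesis rose in 3 of 13, 6 adjusted over the list alone (median 0.33, adjusted p = 0.000877; adjusted p = 0.265 with an estimated correlation), HEMA1 to 77.5 ± 29.5 FPKM (1.28 ± 0.25), a list call lost with nuclear genes rescaled (0.353). PORB rose from 34 ± 5.36 to 62.6 ± 7.36 FPKM (0.87 ± 0.19). Chloroplast-encoded genes had a median of 0.52 and a camera direction of up, with 0 of 86 called and 0 adjusted over the list alone (adjusted p = 1.45e-06; adjusted p = 0.559 with an estimated correlation). Root markers had a median of 0.41, with 0 of 14 called and 0 adjusted over the list alone (adjusted p = 0.0048; adjusted p = 0.567 with an estimated correlation).

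Of the 13 lists called, 4 were up and 9 down (adjusted p = 0.259 to 0.833 with an estimated correlation). Limma called 1609 genes between HS+SA187 and HS, 611 higher and 998 lower, and 26.1% of genes did not overlap (10% by chance). Nuclear rescaling moved the median of all genes from −0.0093 to 1.24 and left 27 calls. Its sum, set mostly by AT2G01021, was 4.44, 1.84 and 25.6 M in HS and 0.772, 0.698 and 6.81 M in HS+SA187. So it cannot decide whether the changes here hold, which are relative to the other genes of the deposited scale. The count was 1071, 838 and 1062 without HS replicate 1, HS+SA187 replicate 2 and HS+SA187 replicate 3.

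**Figure D4:**
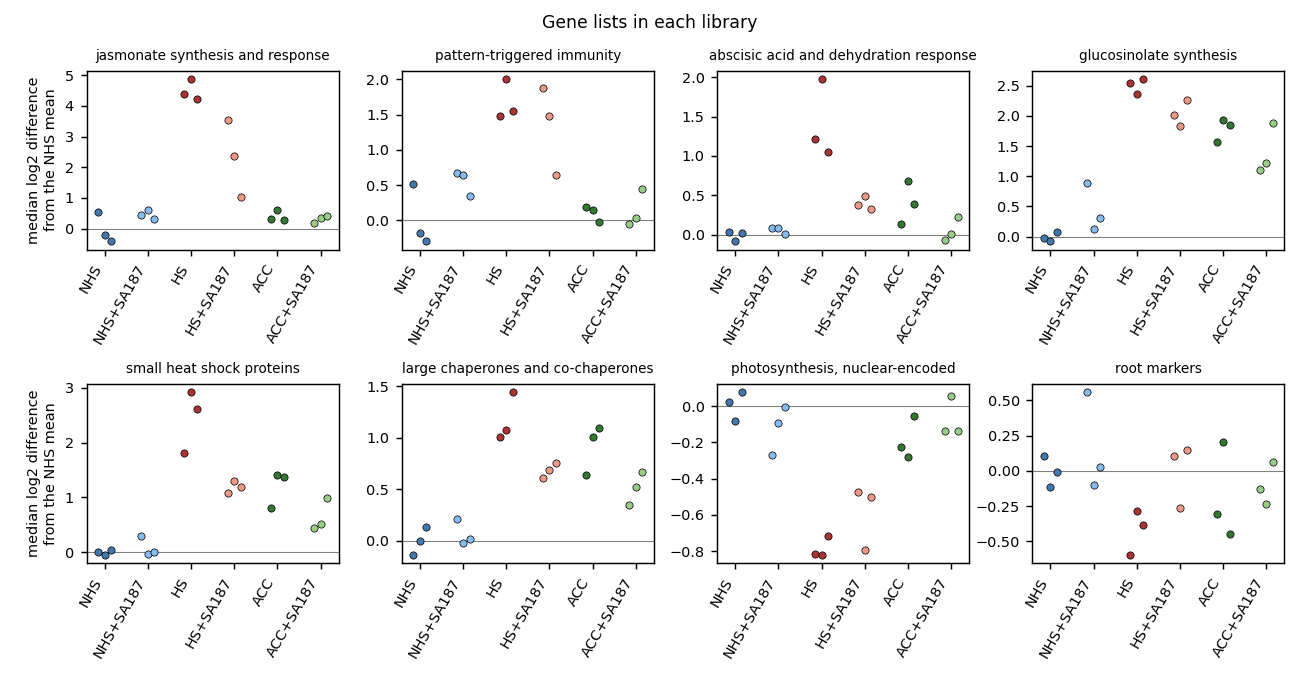
Points give, for 8 gene lists, the median log2 difference of the members in each library from the NHS mean, by group. In HS+SA187 the large chaperones lie below HS by a median of −0.63 per gene (0.89 with nuclear genes rescaled).

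Fold changes of HS+SA187 against HS and of ACC against HS correlated across genes at r = 0.734 (jackknife SE 0.19), where unchanged groups set against the same 3 HS libraries gave a simulated r of 0.489. The covariance was 0.294 against a simulated 0.0484. They shared 438 higher and 899 lower genes, against 48.3 and 149 for independent lists. Genes are not independent replicates, and as 3 controls cannot be split into parts of at least 2 libraries, part of the excess may come from the shared controls. With HS against NHS, a pairing chosen after the data were seen, the correlation was r = −0.748 (jackknife SE 0.13; simulated r = −0.502; covariance −0.349 against a simulated −0.0505), and the same caution on shared controls applies. Of the genes in both sets of calls, 972 were lower with SA187 and higher in HS (316 for independent lists) and 386 the other way (58.6 for independent lists). Pairings without a shared library gave r = −0.203 (SE 0.089) between HS+SA187 against HS and ACC against NHS, r = −0.032 (SE 0.28) between HS+SA187 against HS and NHS+SA187 against NHS, and r = −0.403 (SE 0.2) between NHS+SA187 against NHS and ACC against HS.

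ACC+SA187 against ACC asked what the bacterium changed in acclimated seedlings. RAB18, a dehydrin of abscisic acid response, fell from 18.7 ± 7.24 to 1.57 ± 0.806 FPKM (−2.92 ± 0.45, adjusted p = 0.028), and LTP3 from 24.7 ± 4.45 to 3.08 ± 3.41 FPKM (−2.95 ± 0.49, adjusted p = 0.032). HIS1-3, a linker histone gene, fell from 30 ± 5.74 to 6.87 ± 3.22 FPKM (−2.03 ± 0.32), and HSP70-4 from 23.2 ± 5.07 to 7.74 ± 1.36 FPKM (−1.46 ± 0.23, adjusted p = 0.028). LTP4 fell from 13.6 ± 4.55 to 0.584 ± 0.562 FPKM (−3.2 ± 0.48). HSP90.1 fell from 6.74 ± 1.01 to 2.89 ± 0.664 FPKM (−1 ± 0.16). PDF1.2, a defensin gene, was the only gene called higher, with 1.47, 3.47 and 6.21 FPKM in ACC+SA187 against 0.116, 0 and 0 in ACC (adjusted p = 0.039). All of these calls were lost without ACC replicate 2 (adjusted p = 0.0822 to 0.126), ACC replicate 3 (0.182 to 0.204), ACC+SA187 replicate 1 (0.0616 to 0.259) or ACC+SA187 replicate 2 (0.198 to 0.257). PDF1.2 was also lost with a replicate block (0.0878).

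As lists, flavonoid synthesis had a median of −0.66 with 0 of 12 called and 10 lower adjusted over the list alone (adjusted p = 5.37e-13; adjusted p = 0.259 with an estimated correlation). Large chaperones fell in 2 of 19, 7 adjusted over the list alone (median −0.42, adjusted p = 6.79e-12; adjusted p = 0.379 with an estimated correlation), and abscisic acid genes in 1 of 21, 8 adjusted over the list alone (median −0.45, −0.289 without ACC replicate 2, adjusted p = 8.32e-10; adjusted p = 0.259 with an estimated correlation). Iron genes fell in 1 of 17, 8 adjusted over the list alone (median −0.39, adjusted p = 2.15e-06; adjusted p = 0.379 with an estimated correlation), and that median was −0.219 and −0.791 without ACC replicate 2 or 3 and −0.973 without ACC+SA187 replicate 3. Camera called 12 lists, 4 up and 8 down (adjusted p = 0.259 to 0.755 with an estimated correlation). Limma called 14 genes, 1 higher and 13 lower, with 977 at an unadjusted p under 0.05 (807 by chance) and 10.2% of genes not overlapping (10% by chance), beside 284 genes in the authors' Cuffdiff tables. The count was 0 without ACC replicate 2, ACC replicate 3, ACC+SA187 replicate 1 or ACC+SA187 replicate 2, and 38 without ACC+SA187 replicate 3. The share higher was 7.14% as deposited and 24.2% after quantile normalization (33 calls).

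Whether the effect of SA187 differed between regimes was asked of the interaction. EXPA1 differed between HS and NHS by 2.45 ± 0.38 (adjusted p = 0.0034), and AOC1 by −4.44 ± 0.71 (adjusted p = 0.0041). Between ACC and HS, MYB74 differed by 3.22 ± 0.49 (adjusted p = 0.0046), and the lipid transfer protein gene LTP4 by −4.09 ± 0.68 (adjusted p = 0.0099). For HS and NHS, jasmonate genes had a median difference of −2.59 with 10 of 20 lower, 17 adjusted over the list alone (adjusted p = 2.34e-12; adjusted p = 0.379 with an estimated correlation), and small heat shock proteins one of −1.23 with 6 of 13 lower, 11 adjusted over the list alone (adjusted p = 4.72e-07; adjusted p = 0.379 with an estimated correlation).

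For the SA187 effect at HS minus that at NHS, limma called 620 genes, 94 higher and 526 lower, and the share higher, 15.2%, was 26.4% after median-of-ratios scaling and 36.6% after quantile normalization, the median of all genes moving to 0.064 from −0.095, and to 0.51 with 9 calls under nuclear rescaling. The count was 212 and 310 without NHS replicate 2 or 3, 325 and 337 without NHS+SA187 replicate 1 or 2, 298 without HS replicate 2, and 1213, 273 and 346 without HS+SA187 replicate 1, 2 or 3. For ACC minus HS it was 120, 96 higher and 24 lower, and 429, 59 and 77 without HS+SA187 replicate 1, 2 or 3, 50 without ACC replicate 1 and 64 without ACC+SA187 replicate 2, while nuclear rescaling moved the median of all genes from −0.023 to −1.37 with 12 calls. For ACC minus NHS limma called 0 genes, with 1158 at an unadjusted p under 0.05 (807 by chance), and 24 without ACC+SA187 replicate 3 and 1 without ACC+SA187 replicate 1. No second test of single genes was run on the interactions. Camera called 13 lists for HS minus NHS, 5 up and 8 down (adjusted p = 0.259 to 0.838 with an estimated correlation), and 11 lists for ACC minus HS, 7 up and 4 down (adjusted p = 0.379 to 0.833 with an estimated correlation). For ACC minus NHS it called 11, 4 up and 7 down (adjusted p = 0.379 to 0.861 with an estimated correlation). Flavonoid synthesis had a median of −0.96 there with 0 of 12 called and 9 lower adjusted over the list alone (adjusted p = 8.11e-09; adjusted p = 0.379 with an estimated correlation), and glucosinolate synthesis one of −0.74 with 0 of 16 called and 6 lower adjusted over the list alone (adjusted p = 3.43e-08; adjusted p = 0.4 with an estimated correlation). The effect of SA187 under HS and under ACC correlated across genes, which are not independent replicates, at r = 0.304 (jackknife SE 0.11), with 7 genes lower in both, against 0.804 for independent lists.

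Heat memory genes were fixed as a question of their own. HSP101 (AT1G74310, chromosome 1, 27935298 to 27940190) was at 0.752 ± 0.268 FPKM in NHS, 8.17 ± 2.53 in HS, 2.88 ± 0.609 in ACC, 2.74 ± 0.327 in HS+SA187 and 1.81 ± 0.314 in ACC+SA187. It rose in HS (2.36 ± 0.18), in ACC (1.15 ± 0.18, adjusted p = 0.00098) and in HS+SA187 against NHS+SA187 (1.05 ± 0.18, adjusted p = 0.0019), and neither ACC+SA187 against NHS+SA187 (0.64 ± 0.18, adjusted p = 0.064, and −0.14 with nuclear genes rescaled) nor ACC+SA187 against ACC (−0.46 ± 0.18, adjusted p = 0.7) passed. HSP18.2 (AT5G59720, chromosome 5, 24062577 to 24063277) rose in HS from 0.388 ± 0.213 to 6.39 ± 2.09 FPKM (2.39 ± 0.23), was lower in ACC than in HS (1.86 ± 0.621 FPKM, adjusted p = 0.00051), and its difference between HS+SA187 and HS did not pass (3.36 ± 0.706 FPKM, adjusted p = 0.057). HSP22.0 (AT4G10250, chromosome 4, 6370343 to 6371291) was listed at 0 in all NHS libraries and at 1.18, 1.73 and 3.47 FPKM in HS. HSFA2, the heat shock factor that sustains the memory (AT2G26150, chromosome 2, 11135682 to 11137396), stayed below the filter and was not tested: it was at 0.0297 ± 0.0219 FPKM in NHS, 1.12 ± 0.302 in HS, 0.234 ± 0.142 in ACC, 0.192 ± 0.0503 in HS+SA187 and 0.117 ± 0.0255 in ACC+SA187. The plastid small heat shock protein HSP21 was listed at 0 in NHS and at 0.442, 0.463 and 1.4 FPKM in HS, and APX2, a cytosolic ascorbate peroxidase, stayed at 0.163 ± 0.115 FPKM in HS, and neither was tested.

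The authors' own comparison tables list 17090 gene results over the 9 comparisons, 14749 of them among genes tested here. Of these, 14735 had the same sign and 10138 were called. For HS against NHS, 3483 of 4007 were called, for HS+SA187 against HS 923 of 1366, for ACC+SA187 against ACC 13 of 242 and for NHS+SA187 against NHS 0 of 280.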

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

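The tests of HS+SA187 replicate 3, of the calls between NHS+SA187 and NHS and of the organelle share were chosen after the results were seen, and the scaling test and the random regroupings before.

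The effect of SA187 differed between HS and NHS for 620 genes in the interaction test of limma. Genes named by the fixed rule were EXPA1 (2.45), HBI1 (1.83) and BBX14 (1.79) upward and LOX4 (−4.46), AOC1 (−4.44) and CYP94B3 (−4.31) downward. By camera at the preset correlation 13 lists differed, 5 up and 8 down, among them small heat shock proteins (−1.23), large chaperones (−0.656), heat memory genes (−1.01), abscisic acid (−0.973, −0.587 without HS replicate 2), jasmonate (−2.59), chlorophyll synthesis (0.348), glucosinolates (−0.991) and flavonoids (−0.828, −0.53 without NHS+SA187 replicate 1). With an estimated correlation none of the lists was called (adjusted p = 0.259 to 0.838). With nuclear genes rescaled, large chaperones were at 0.138, glucosinolates at 0.0211 and flavonoids at 0.126. EXPA1 and AOC1 held with any library left out, while HBI1, BBX14, LOX4 and CYP94B3 were each lost in 8 to 10 of 12 such refits, for example without NHS replicate 2 (adjusted p = 0.0786, 0.107, 0.129 and 0.0992). Heat memory genes were lost without HS replicate 3 (0.0601) and flavonoids without HS+SA187 replicate 1 (0.0637). Of 100 regroupings of the libraries, 2 gave at least as many genes, the highest other count being 811, so chance was excluded at a share under 0.05.

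Between ACC and HS the effect of SA187 differed for 120 genes, among them AOC1 (3.89), RAP2.6 (3.5), MYB74 (3.22), LTP4 (−4.09), RAB18 (−2.94) and GASA6 (−2.39). Camera called 11 lists, 7 up and 4 down, among them abscisic acid (0.307), jasmonate (2.06, 1.32 without HS+SA187 replicate 3) and cell wall loosening (−0.546). None of the lists was called with an estimated correlation (adjusted p = 0.379 to 0.833). Abscisic acid was at −1.08 with nuclear genes rescaled. MYB74 and LTP4 held with any library left out, AOC1 was lost without ACC replicate 1 (adjusted p = 0.0519) or ACC+SA187 replicate 2 (0.0534), and RAP2.6, RAB18 and GASA6 were lost in 7 to 10 of 12 refits, for example without ACC replicate 1 (0.125, 0.0667 and 0.0901). There 11 of 100 regroupings gave at least as many, the highest being 933, so chance was not excluded. A regrouping with several times the real count points to a sample structure that was not tested. Between ACC and NHS the 0 genes were matched by 100 of 100 regroupings, the highest being 4.

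HS+SA187 replicate 3 lay nearer to the ACC libraries than to the other libraries of its group. Of the ACC and ACC+SA187 libraries 0 lay below 0.5 on the axis from HS to ACC. That bound rests on HS+SA187 replicates 1 and 2 (0.17 and 0.43), so a swap of replicate 3 stays open. A single wrong label stays open: its place of 0.77 was below the lowest ACC or ACC+SA187 library (0.87) by more than their SD of 0.08, but its correlation with the ACC mean, 0.964, lay within the range of the ACC libraries (0.957 to 0.973), a criterion added after the place had been seen. Against such a label stand its scores for jasmonate (1.024; 0.191 to 0.621 in the ACC and ACC+SA187 libraries) and photosynthesis (−0.502; −0.278 to 0.058) and LOX4 at 2.37 FPKM (0.478 ± 0.0949 in ACC), but it lay outside their range for 11 of 28 lists and each of those libraries outside that of the others for 3 to 20. The place of 0.77 also lay within the NHS+SA187 libraries (0.7 to 0.88, r = 0.931 with their mean), a swap with which was not tested. Without this library, HS+SA187 against HS had 1062 calls.

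Limma called no gene between NHS+SA187 and NHS, where the authors' tables hold 304. That 1 library hides the calls was excluded, as the highest count with any of the 6 left out was 0. As a covariate (1 call) depth adjusts level, not precision, and stays open. Of the authors' genes tested here, 38.2% had groups that did not overlap, against 71.5 to 89.6% in the other comparisons, so a spread between replicates wider than the authors' test allowed for may explain the difference. How that test estimated the spread is not given in the sources used here, and this stays open.

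Most genes called between HS and NHS were higher in HS. With 1 scaling factor per library as the whole cause, the share among 2-fold calls would lie within 10 points of 50% after median-of-ratios scaling, and above 65% it would be excluded. The share was 66.8%, outside what the explanation needs, but its range with 1 library left out (62.7 to 69.5%, computed after the share was seen) reached below that bound, so it was not excluded either. After quantile normalization the share was 56.5%, within what the explanation needs. A few organelle or rRNA genes taking most fragments stay open too. Within groups the scaling factor and the organelle share correlated across the 18 libraries at r = 0.108 (permutation p = 0.8, jackknife SE 0.32) and rho = 0.073 (p = 0.81), and at r = 0.083 without the 2 farthest libraries, but organelle genes and AT2G01021 together held 97.7 to 99.5% of FPKM in every library, so that share does not measure what was left for other genes.

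Pairwise comparisons allow only 10 splits of 3 against 3, which is too few to tell chance. The real split alone (1 of 10) reached its count in each of these, the highest other count being 0 for HS against NHS, 1 for ACC against NHS, 2 for ACC against HS, 110 for HS+SA187 against NHS+SA187, 0 for ACC+SA187 against NHS+SA187, 1 for ACC+SA187 against HS+SA187, 2 for HS+SA187 against HS and 2 for ACC+SA187 against ACC. For NHS+SA187 against NHS all 10 of 10 reached 0, as any split must, the highest being 1.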

How the results depend on the processing

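No alternative below was chosen after its result was seen, save depth as a covariate, the genes listed at 0 left out and 1 added correlation. The cause of each shift was not tested unless the construction shows it.

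With nuclear genes rescaled, where AT2G01021 held 54.4 to 95.2% of the nuclear sum and so set the factor, the calls were 115 for HS against NHS, 10 for ACC against NHS, 92 for ACC against HS, 119 for HS+SA187 against NHS+SA187, 44 for ACC+SA187 against NHS+SA187 and 620 for ACC+SA187 against HS+SA187. They were 14 for NHS+SA187 against NHS, 27 for HS+SA187 against HS, 3 for ACC+SA187 against ACC, and 9, 7 and 12 for the interactions of HS with NHS, ACC with NHS and ACC with HS. The sign turned for ACC+SA187 against NHS+SA187 in BIP1 (−0.53), RPL15 (−0.46) and emb1473 (−0.63). For ACC+SA187 against HS+SA187 it turned in LHCB1.4 (−0.12), RPE (−0.09), ASN1 (−0.21), LHCA2 (−0.55), PORB (−0.48), CAO (−0.77) and AT5G24490 (−0.59). For HS+SA187 against HS it turned in HSP70-4 (0.3), XTR6 (0.14), HSP101 (0.37), WIP4 (0.49), MYB34 (0.73), FMOGS-OX1 (0.54), F3PH (0.46) and PAP1 (0.19). Camera's direction, which sets a list against all other genes, turned for the list cytosolic ribosomal proteins in ACC vs NHS (median −0.0978) and for chlorophyll synthesis in the interaction of ACC with HS (median −2.04), where neither was called any more. Other medians changed sign with camera's direction kept, as given in the report. Correlations were 0.407 for HS+SA187 against HS with NHS+SA187 against NHS, and 0.515 for HS+SA187 against HS with ACC against HS.

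With the groups of the contrast only, calls were 1280 for ACC against NHS, 981 for HS+SA187 against NHS+SA187, 1011 for ACC+SA187 against NHS+SA187, 134 for ACC+SA187 against HS+SA187, 373 for HS+SA187 against HS and 1 for ACC+SA187 against ACC, and 293, 3 and 53 for the interactions of HS with NHS, ACC with NHS and ACC with HS. At a 2-fold threshold they were 2828 for HS against NHS, 678 for ACC against NHS, 1644 for ACC against HS, 707 for HS+SA187 against NHS+SA187, 336 for ACC+SA187 against NHS+SA187, 732 for ACC+SA187 against HS+SA187 and 649 for HS+SA187 against HS. Depth as a covariate gave 368 for ACC+SA187 against NHS+SA187, 1 for NHS+SA187 against NHS and 76 for the interaction of ACC with HS. Without a filter there were 2 calls for NHS+SA187 against NHS and 0 for ACC+SA187 against ACC, and a pseudocount of 0.1 gave 45 for the interaction of ACC with HS. Median-of-ratios scaling gave 26 and quantile normalization 33 for ACC+SA187 against ACC, and median-of-ratios scaling gave 1 for the interaction of ACC with NHS. Quantile normalization turned camera's direction for chloroplast-encoded genes in HS+SA187 against NHS+SA187 (0.0757), in ACC+SA187 against HS+SA187 (−0.147) and in the interaction of ACC with NHS (0.0863), and the list photosynthesis, nuclear-encoded in ACC+SA187 vs ACC (−0.0709). Of 154 list calls, 0 were kept with an estimated correlation, 147 with median-of-ratios scaling and 133 with quantile normalization. With nuclear genes rescaled, where organelle lists could not be tested, 111 were kept, 26 were lost and 2 were lost with camera's direction turned.

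With 1 library left out, calls ran from 1331 to 2478 for ACC against NHS, 937 to 2322 for HS+SA187 against NHS+SA187, 101 to 460 for ACC+SA187 against NHS+SA187, 166 to 2158 for ACC+SA187 against HS+SA187, 838 to 1899 for HS+SA187 against HS and 0 to 38 for ACC+SA187 against ACC. For the interactions they ran from 212 to 1213 (HS with NHS), 0 to 24 (ACC with NHS) and 50 to 429 (ACC with HS). The correlation of HS against NHS with HS+SA187 against NHS+SA187 ran from 0.614 to 0.807, and that of HS+SA187 against HS with ACC against HS from 0.511 to 0.786. The median of the list mitochondrion-encoded genes in NHS+SA187 vs NHS ran from −0.195 to 0.241, and that of the list mitochondrion-encoded genes in SA187 effect at ACC minus at HS from 0.0528 to 0.323.

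Taken over all groups, replicate numbers did not pair the libraries: 18 of 45 pairs with the same number had a correlation over 0.1 (−0.33 to 0.442), and 4 of 18 libraries had their best partner under the same number. HS and ACC alone had all 3 pairs over 0.1 (0.299, 0.222 and 0.173). With a replicate block the calls were 6728 for HS against NHS, 2682 for ACC against NHS, 3728 for ACC against HS, 2025 for HS+SA187 against NHS+SA187, 813 for ACC+SA187 against NHS+SA187, 1303 for ACC+SA187 against HS+SA187, 0 for NHS+SA187 against NHS, 1620 for HS+SA187 against HS and 11 for ACC+SA187 against ACC, and 526 for the interaction of HS with NHS. The block kept 153 of 154 list calls and lost hypoxia in ACC against HS (adjusted p = 0.0578).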

Other observations

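The comparison of PDF1.2 with jasmonate genes was chosen after the values were seen. PDF1.2, a defensin gene often used as a marker of jasmonate and ethylene signalling, was at 0, 0.061 and 0 FPKM in the HS libraries, where all 20 jasmonate genes rose against NHS, and at 6.14, 4.96 and 2.6 FPKM in HS+SA187. In NHS it was at 1.47, 4.17 and 1.42 FPKM.

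In the authors' tables for NHS+SA187 against NHS, ZAT10 was at 181 against 70.3 FPKM, JAZ1 at 33 against 16.4, ACS6 at 86.2 against 41.9 and WRKY70 at 31.6 against 11.5, none of which limma called here. HSFA2 was at 0.358 against 1.95 FPKM in the authors' table for HS+SA187 against HS.

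The plastid transcripts PSBF and PSBL had the highest mean FPKM over all libraries (25400000 and 13800000), followed by the nuclear gene AT2G01021 (4560000). ORF31 was at 76657, 100819 and 39501 FPKM in NHS, 0, 8472 and 0 in HS, and 0 in all ACC libraries, and the Rubisco small subunit gene RBCS1A was listed at 0 in NHS replicate 3 and ACC+SA187 replicate 2.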
